A study of Caenorhabditis elegans with 2 samples.

How the data were processed

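The data were peak lists from chromatin immunoprecipitation and sequencing of EFL-1::GFP in L1 larvae, with 2 libraries of 1 group. Per the labels, they were biological replicates 1 and 2, and the size range was 150 to 350 bp. The labels name the antibody target as efl-1 and describe the experiment as directed at eGFP-efl-1, so which antibody was used is left open. Per the text files deposited with each library, a list of peaks and background was made from the alignment of each replicate and from both alignments pooled, each with a control alignment shared by the replicates. The same text files say that an optimal list thresholded by the irreproducible discovery rate (IDR) was derived from the pooled list and both replicate lists. The peak caller, the aligner and the IDR threshold were not given in the sources used here, and the control library and the signal tracks were not analysed here.

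Each list was in the narrowPeak format. The score of a peak is the authors' own value in the seventh column, deposited without a stated scale, and was used to rank and describe peaks. Scores of separately called lists need not share a scale. The −log10 of a q-value in the ninth column was deposited by the authors and reached a shared maximum in each list. Summit offsets in the tenth column are the authors' other deposited value, counted in bp from the start of the peak. Lists in the ce11 build were used for all results, and those in the older build only for the number of peaks and the agreement of replicates. No coordinates were converted. The peak lists carry no read counts, so that the depth of the libraries was unknown.

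Genes and transcript starts were taken from Ensembl release 115 of the WBcel235 assembly, which is the ce11 sequence, and the sequence from the RefSeq copy of the same assembly. The 19973 protein-coding genes of the 6 nuclear chromosomes were used. A gene had a promoter peak when a reproducible summit lay from 500 bp upstream to 100 bp downstream of any of its annotated transcript starts, and its score was that of the strongest such peak. Genes were counted by gene identifier, and 205 genes shared a symbol with another. A summit could count for several genes, and operons were not considered.

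Promoter share was tested against 1000 random placements on the same chromosome. Cores were sought on both strands within 50 bp of the summit and compared with a window displaced by 500 bp to a side drawn at random, with a two-sided exact McNemar test, and each core read backwards served as a control. GC-matched promoters were windows 150 bp upstream of the start of genes without a peak, matched in steps of 2 percentage points. Each of 18 gene lists, 10 of them target lists and 8 comparison lists, was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 18. Odds ratios had 0.5 added to each cell. The median score of the bound members of the 12 lists with at least 5 was compared with 100000 random draws of bound genes (two-sided, drawn with replacement), with adjustment over the 12. The top and bottom groups of 20% of peaks were compared by 100000 permutations. The gene lists, cores and these tests were chosen before the data were examined. Added after the data were seen were the CHR core in groups by peak strength, the tests within the top and bottom 20% of peaks, the joint occurrence of the cores, the rank correlation in the top 20% and the peaks by kind of location. Calls used an adjusted p of 0.05.

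The genes named were all members of the DREAM list, the 10 strongest peaks with the genes whose promoters held them, the 3 bound members with the strongest peak in each other target list, the strongest bound member of each comparison list, and unc-119. Other genes were named after their values were seen, namely genes that share a peak with a named gene, the list members given as examples of families or of genes without a peak, and the chemoreceptor genes with a peak nearer another start. The second member of a pair of neighbours was kept where both promoters held the summit.

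The tests were run on simulated data first. Over 100 simulations on 19973 genes, a gene list with raised binding passed the test in 96% and unchanged lists in 0.529%. A core planted in 19.7% of 3824 windows was recovered as a difference of 18.7 percentage points, and with none planted the difference was −0.288 (exact McNemar test, p = 0.521). A list with tripled scores among 2947 bound genes passed the permutation test of medians (adjusted p = 0.0012), and 0 unchanged lists passed. Shuffled scores gave p = 0.888 in the permutation test of strength over 3824 peaks. Random positions differed from the random mean by 0.437 percentage points in promoter share.

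The alternatives were the strongest 3824 entries of either replicate list in place of the reproducible list, the stronger 50% of peaks, promoters 2 times or 0.5 times as long on both sides of the start, the nearest start within 2000 bp, a background of genes with a pooled-list entry in the promoter, core windows of 25 and 100 bp, a displacement of 1000 bp, GC-matched promoters, the longer core TTTSSCGC, stricter overlaps of replicates and the lists of the older build. After the data were seen, the 1200 reproducible peaks that overlap an entry with a −log10 q above 2 in each replicate list were added as a further alternative. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.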

Results

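Chromatin immunoprecipitation followed by sequencing was used to map where EFL-1, an E2F-family transcription factor and subunit of the DREAM complex, occupied the genome of first-stage (L1) Caenorhabditis elegans larvae. The animals were whole, mixed-sex larvae of strain YL424, an unc-119 mutant with an inserted transgene that carries EFL-1 fused to GFP and FLAG under the efl-1 promoter and 3' UTR together with a functional unc-119 gene. The series held 1 group of 2 libraries, labelled biological replicates 1 and 2, and no other stage, strain or treatment. All comparisons were therefore made between places in the genome, and no test between conditions was possible. The files were peak lists, which carry no read counts, so the depth of the libraries was unknown. The p-values and intervals given here cover counting error over peaks or genes only, not the spread between animals.

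The reproducible list, which the authors derived from both replicates, held 3824 peaks with a median width of 336 bp in the ce11 build. The strongest peak of the genome, with a score of 7157 on the authors' scale, lay at chromosome II 4999124 to 4999558, with its summit at −184 bp from the start of citk-2 (WBGene00019087). It was followed by the peaks of rpl-3, which encodes a large-subunit ribosomal protein (score 5952), dld-1, which encodes dihydrolipoamide dehydrogenase (5624), cdc-48.1, an AAA ATPase of protein degradation (5411), and eelo-2 (5162). The next were tba-2, an alpha tubulin gene (4541), a peak between Y53F4B.11 and Y53F4B.9 (4391), syf-3, a splicing factor gene (4372), a peak between T23F6.3 and rbd-1 (4249.8), and F48A11.4 (4219). All 10 of these summits were in promoters, at −307 to −76 bp from a start of those genes. The top peak scored 70.7 times the median peak. Chromosome III held 842 peaks, chromosome I 838, chromosome IV 652, chromosome II 639, chromosome V 567 and the X chromosome 286.

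The strongest sites stood out in both replicates, and at a −log10 q above 2 the weak ones rested on replicate 2. The peak of cdc-48.1 ranked first in the replicate 1 list and 5 in the replicate 2 list, and that of citk-2 ranked 2 and 1. Among the top 20% of reproducible peaks, 99.1% overlapped an entry with a −log10 q above 2 in each replicate list, but among the bottom 20% this share was 0.654%. Over all 3824 peaks, 1201 (31.4%) overlapped such an entry of replicate 1 and 3815 (99.8%) such an entry of replicate 2. Replicate 1 had only 1196 such entries, which limits how many peaks could have this support. Entries of replicate 1 at any q overlapped 2917 of the peaks (76.3%). Across the 2911 peaks with an entry in both lists, Spearman's rho between the replicates' scores was 0.835, and it was 0.925 across the 764 of them in the top 20%. These correlations are across peaks, which are not independent replicates. The strongest 3824 entries of replicate 1 overlapped 54.8% of the reproducible peaks and those of replicate 2 overlapped 93.8%. The reproducible list was identical to the pooled-list entries at or above its lowest score of 35.7, and so it ranked peaks by the pooled data.

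**Figure D1:**
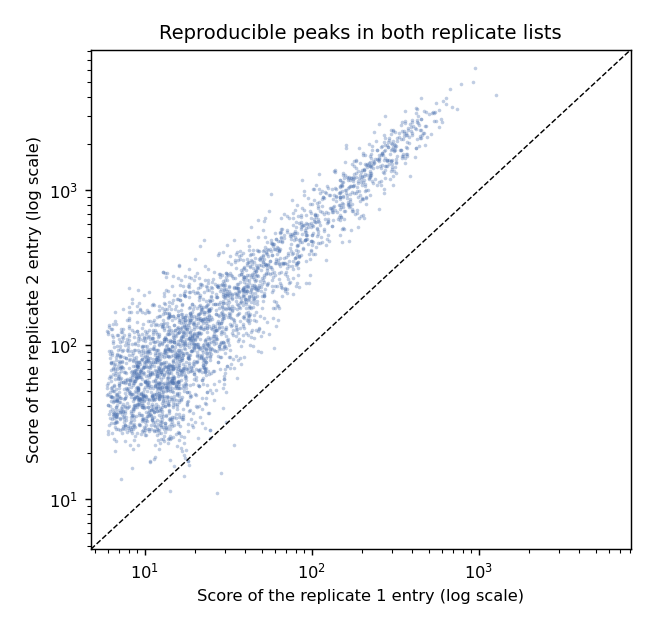
Score of the overlapping replicate 1 entry (x axis, log scale) against that of the replicate 2 entry (y axis, log scale), in the authors' score units, for each of the 2911 reproducible peaks found in both replicate lists, with a dashed line of equal scores. Scores rise together (Spearman's rho 0.835), and 2903 of the points lie above the line.

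EFL-1::GFP peaks were concentrated at the promoters of protein-coding genes. Of the 3824 summits, 2321 (60.7%) lay between 500 bp upstream and 100 bp downstream of an annotated transcript start. Summits placed at random on the same chromosome fell there in 14.3% ± 0.585 of cases (SD of 1000 placements), so that the observed share was 4.25 times the random one (one-sided permutation p = 0.000999, the smallest that 1000 placements allow). The stronger peaks were more often promoter peaks, with 89.4% of the top 20% against 38.5% of the bottom 20%. Of all summits, 905 (23.7%) were outside protein-coding genes and their promoters, 534 were in introns outside promoters, and 7 (0.183%) were in coding exons outside promoters. Other kinds of genes were not considered. Peaks supported by an entry with a −log10 q above 2 in each replicate, a selection made after the data were seen, were promoter peaks in 84.8% of cases.

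The promoters of 2947 of 19973 protein-coding genes (14.8%) held a reproducible summit. Many neighbouring genes shared a peak: 670 summits lay in the promoters of 2 or more genes. For example, the peak at chromosome IV 10734526 to 10734898 had its summit at −130 bp from the start of orc-5, a subunit gene of the origin recognition complex, and at −498 bp from that of cyb-1, a B-type cyclin gene. Which of the genes at a shared peak it serves was not tested. With only the 1200 peaks supported in each replicate, a selection made after the data were seen, the number of genes was 1385.

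Genes of the DREAM complex itself were among those with promoter peaks. Of its 8 members, lin-9 (score 1693), lin-54, which encodes the subunit that binds the CHR element (1375), lin-53 (1188), lin-35, the worm's Rb-like pocket protein (728), and dpl-1, the DP partner of EFL-1 (522), had one, and efl-1, lin-37 and lin-52 had none. No list used here held any entry over efl-1 or near it, so its promoter could not be assessed, though it counts among the 8. The 5 of 8 (62.5%, 95% Wilson interval 30.6% to 86.3%) compared with 14.7% of other genes (odds ratio 9.09, two-sided Fisher's exact test, adjusted p = 0.00432 over 18 lists). All 5 peaks were in the top 20% of scores and supported in each replicate. Their median score was 7.07 times that of other bound genes (permutation test, adjusted p = 0.0614), and 4.44 times in the replicate 1 list alone (adjusted p = 0.136). By the same exact test the call on the number of members was lost against genes with any pooled-list entry in the promoter (adjusted p = 0.155), with each summit assigned only to its nearest start (adjusted p = 0.137) and with a narrower promoter (adjusted p = 0.0636), and the adjusted p over all alternatives was 0.000149 to 0.155.

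DNA replication genes carried EFL-1::GFP at nearly all of their promoters. Peaks were present at 36 of 42 (85.7%), among them all 7 mcm genes, which include the replicative helicase subunits, and 4 of 5 orc genes. The strongest were at pcn-1, which encodes the sliding clamp PCNA (WBGene00003955, chromosome IV 4049480 to 4049940, score 2745), orc-5 (2482) and psf-3, a GINS subunit gene (2199.6). The odds ratio against other genes was 32.8 (95% interval 14.2 to 75.7, Fisher's exact test, adjusted p = 9.46e-24). The median peak of these genes was 4.21 times as strong as that of other bound genes (permutation test, adjusted p = 0.00048). The excess in number passed the test in every alternative run (odds ratio 10.3 to 42.5). Of the 12 lists compared by score, 5 passed as stronger, against 2 of 11 in the stronger 50% of peaks and 0 of 10 among peaks supported in each replicate. The ratio for replication genes was 2.42 and 1.52 there, but both selections are made on the score that is compared.

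Of 58 mitosis and chromosome segregation genes, 46 had a promoter peak (79.3%, odds ratio 21.8, Fisher's exact test, adjusted p = 3.7e-27), with 33 by nearest start (odds ratio 7.47) and 54 with the wider promoter (odds ratio 56.5). The strongest members were knl-3, a kinetochore gene (score 2295), sep-1, which encodes separase (2194), and kbp-4, a kinetochore gene (2055). Peaks were also present at the Aurora kinase genes air-1 and air-2, the cohesin gene scc-1 and the centriole gene sas-6. The median of the 46 was 3.52 times that of other bound genes (permutation test, adjusted p = 0.00048). Among peaks supported in each replicate, a selection on the score itself, the ratio was 1.37 (permutation test, adjusted p = 0.402).

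DNA repair and checkpoint genes had promoter peaks at 28 of 45 members (62.2%, odds ratio 9.49, Fisher's exact test, adjusted p = 1.03e-12). The checkpoint clamp loader gene hpr-17 scored 3426, the translesion polymerase gene polh-1 scored 2879.5 and the nuclease gene fan-1 scored 2653. The median of the list was 3.32 times that of other bound genes (permutation test, adjusted p = 0.00448).

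Regulators of the cell cycle had promoter peaks at 11 of 34 members (32.4%, odds ratio 2.83, Fisher's exact test, adjusted p = 0.018), with the highest scores at wee-1.3, an inhibitory kinase of CDK-1 (3696), cyb-1 (2482, the peak shared with orc-5) and cdk-1 (848). The G1 cyclin genes cyd-1 and cye-1, cdk-4 and all 4 cdc-25 genes had no reproducible promoter peak. These genes without a peak were each chosen after its values were seen. The median score of the 11 bound members was 2.81 times that of other bound genes (permutation test, adjusted p = 0.0972), and 1.52 times in the replicate 1 list alone (adjusted p = 0.528). The list's call on number was lost against genes with a pooled-list entry (Fisher's exact test, adjusted p = 0.194) and with the narrower promoter (adjusted p = 0.106, range over the alternatives 0.000496 to 0.194).

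Chromatin and small RNA genes were bound in part. Chromatin regulators had promoter peaks at 19 of 36 members (52.8%, odds ratio 6.47, Fisher's exact test, adjusted p = 2.08e-07), led by mes-2, the worm's Enhancer of zeste (2918), isw-1, a nucleosome remodeller (1717), and set-2, a histone methyltransferase (1388). Small RNA pathway genes had them at 13 of 34 (38.2%, odds ratio 3.64, Fisher's exact test, adjusted p = 0.00121), led by pash-1, a microRNA processing gene (3473), the RNA interference gene rde-4 (894) and mut-2 (603). Median scores were 2.43 times (permutation test, adjusted p = 0.0614) and 1.245 times (adjusted p = 0.634) those of other bound genes. The small RNA call was lost against genes with a pooled-list entry (Fisher's exact test, adjusted p = 0.0704, range over the alternatives 6.98e-06 to 0.0704).

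Meiosis, germ granule and oocyte, and histone genes had no detected excess of promoter peaks over other genes. Meiosis genes had peaks at 4 of 30 (13.3%, odds ratio 0.981, Fisher's exact test, adjusted p = 1), namely him-17 and, with the highest scores, pch-2 (689), syp-3 (172) and syp-2 (70.2). Germ granule and oocyte genes had them at 4 of 37 (10.8%, odds ratio 0.776, Fisher's exact test, adjusted p = 0.774), with spn-4 at 1425, nos-3 at 279.7 and gld-2 at 56.3. Of 72 histone genes, 6 had a promoter peak (8.33%, odds ratio 0.564, Fisher's exact test, adjusted p = 0.175), with his-37 at 349 and his-67 and his-68 sharing a peak at 125. Their median was 0.697 times that of other bound genes (permutation test, adjusted p = 0.496), and in the stronger 50% of peaks, a selection on the score itself, 0.377 times (adjusted p = 0.0141, range over the alternatives 0.0141 to 0.657). In the replicate 1 list alone 3 of the 72 histone genes had a promoter peak (odds ratio 0.377, Fisher's exact test, adjusted p = 0.0594). Histone genes are present in near-identical copies, so the count for them is uncertain. The list passed Fisher's exact test as lower with the wider promoter (adjusted p = 0.0413) and with the nearest start (adjusted p = 0.0301, range over the alternatives 0.0301 to 1).

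Broadly expressed housekeeping genes, chosen as a comparison, also had promoter peaks more often than other genes. Ribosomal protein genes had promoter peaks at 67 of 76 (88.2%, odds ratio 42.0, Fisher's exact test, adjusted p = 3.51e-45), proteasome genes at 27 of 33 (81.8%, odds ratio 24.7, adjusted p = 5.26e-17) and oxidative phosphorylation genes at 28 of 39 (71.8%, odds ratio 14.4, adjusted p = 4.54e-15). The top members were rpl-3 (5952), rpn-11, which encodes a deubiquitinase of the proteasome (2219.5), and cox-5A, a cytochrome c oxidase subunit gene (3882). The median score of ribosomal protein genes was 2.02 times that of other bound genes (permutation test, adjusted p = 0.0054), and those of proteasome (1.34 times, adjusted p = 0.478) and oxidative phosphorylation genes (1.39 times, adjusted p = 0.444) did not pass the test. By the same permutation test the ribosomal call was lost with the narrower promoter (ratio 2.01, adjusted p = 0.267, range over the alternatives 0.0013 to 0.614) and in the stronger 50% of peaks (ratio 1.16, adjusted p = 0.614), and the ratio was 0.724 among peaks supported in each replicate (adjusted p = 0.402). The number of ribosomal protein genes with a peak fell to 17 with the narrower promoter (22.4%, odds ratio 2.64, Fisher's exact test, adjusted p = 0.00282, range over the alternatives 5.26e-50 to 0.00282), and that of oxidative phosphorylation genes to 14 (35.9%, odds ratio 5.098). Over the alternatives the odds ratio was 2.64 to 50.8 for ribosomal protein, 11.1 to 40.4 for proteasome and 5.098 to 18.7 for oxidative phosphorylation genes.

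Genes of differentiated tissues had no detected excess of promoter peaks. Muscle genes had peaks at 3 of 28 (10.7%, odds ratio 0.793, adjusted p = 0.888 by Fisher's exact test), with the myosin chaperone gene unc-45 at 1364, intestine genes at 1 of 31 (3.23%, odds ratio 0.284, adjusted p = 0.105), with erm-1 at 122.6, and neuron genes at 4 of 31 (12.9%, odds ratio 0.945, adjusted p = 1), with snb-1, which encodes synaptobrevin, at 159.9 and the transgene marker unc-119 among the 4. In the replicate 1 list alone the odds ratios were 0.409 for muscle, 0.635 for intestine and 0.368 for neuron genes, with 1, 2 and 1 members bound. The intestine list passed the exact test as lower with the wider promoter (odds ratio 0.226, adjusted p = 0.0413, range over the alternatives 0.0413 to 0.761). Cuticle collagen genes were bound less often, at 4 of 172 (2.33%, odds ratio 0.153, Fisher's exact test, adjusted p = 1.41e-07), and their highest score, 2387 at col-38, belonged to a peak also in the promoter of rpl-5. The collagen call was lost against genes with a pooled-list entry (odds ratio 0.321, Fisher's exact test, adjusted p = 0.0512, range over the alternatives 1.31e-07 to 0.0512), and the odds ratio over the alternatives was 0.0773 to 0.325.

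Chemoreceptor genes had promoter peaks less often than other genes, at 7 of 1309 (0.535%, odds ratio 0.0308, 95% interval 0.0150 to 0.0632, Fisher's exact test, adjusted p = 2.17e-80). In the replicate 1 list alone 11 members had a peak, and the odds ratio was 0.0618, with 0.0222 to 0.0803 over all alternatives. The highest score among them in the reproducible list was 2314 at sri-5. The median of the 7 was 9.19 times that of other bound genes (permutation test, adjusted p = 0.00802). The srr-10 and srd-4 peaks, each gene chosen after its values were seen, lay nearer to the starts of clic-1 and usip-1, and with each summit given to its nearest start the ratio was 0.703 (permutation test, adjusted p = 0.403). In the replicate 1 list alone the ratio was 0.466 (11 genes, permutation test, adjusted p = 0.0481, range over the alternatives 0.00832 to 0.967), and with the wider promoter it was 1.01 (permutation test, adjusted p = 0.967).

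**Figure D2:**
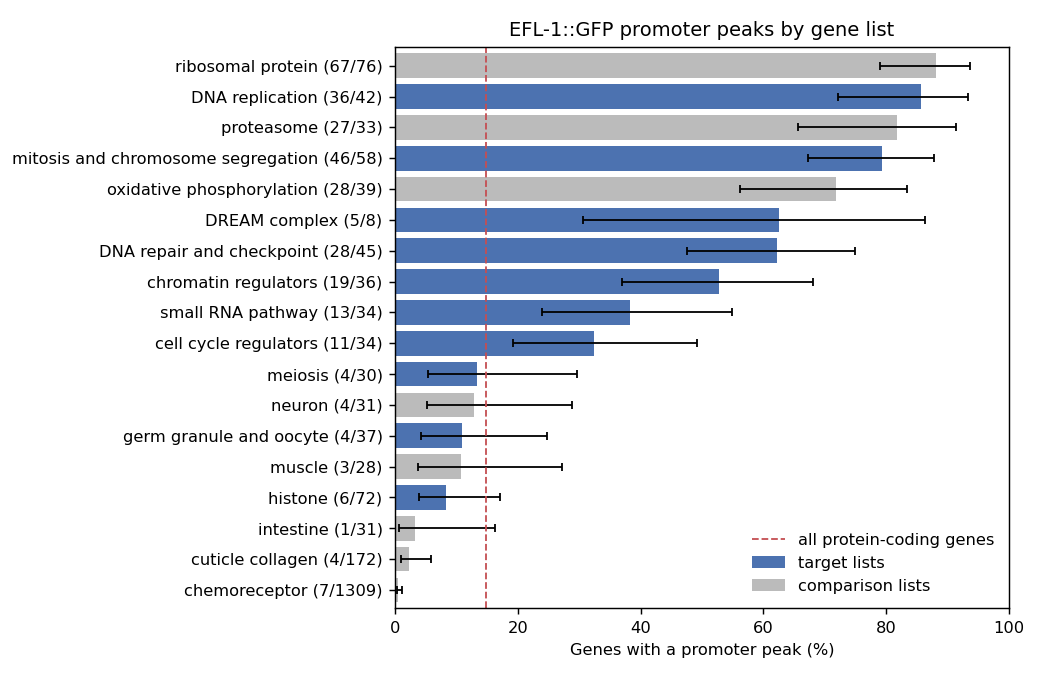
Percent of the genes of each list with a reproducible EFL-1::GFP summit in the promoter (x axis), with bound genes and members in parentheses; bars in blue are target lists and in grey comparison lists, error bars are 95% Wilson intervals and the dashed line marks all protein-coding genes (14.8%). DNA replication genes (85.7%) and ribosomal protein genes (88.2%) lie far above the line and chemoreceptor genes (0.535%) below it.

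Promoter peaks were rarer on the X chromosome than on the autosomes. On X, 174 of 2731 genes had one (6.37%), against 2773 of 17242 autosomal genes (16.1%), an odds ratio of 0.356 (95% interval 0.304 to 0.417, two-sided Fisher's exact test, p = 1.18e-47). Among peaks supported in each replicate, a selection made after the data were seen, the share of X genes was 0.879% and the odds ratio was 0.106.

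The E2F core TTSSCGC (S is C or G) was found near EFL-1::GFP summits at genes such as pcn-1, orc-5, wee-1.3 and mes-2. It lay within 50 bp of 642 of 3824 summits (16.8%), against 4.11% of windows displaced by 500 bp, a difference of 12.7 percentage points (95% interval 11.34 to 14.02, exact McNemar test, p = 1.11e-77). Against promoters without a peak of the same GC content, the comparison share was 6.17% (Fisher's exact test, p = 2.14e-49). The core read backwards, a control of the same composition, was also more frequent at summits, at 9.65% against 1.99% in displaced windows. Its ratio of 4.86 was no lower than the 4.09 of the E2F core, so the excess was not specific to the E2F sequence in that respect, while the difference in percentage points was larger for the E2F core (12.7 against 7.66).

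The E2F core went with peak strength. It was present at 31.0% of the top 20% of peaks and at 17.4%, 13.2%, 11.2% and 11.1% of the following groups of 20%. In the replicate 1 list alone the top and bottom shares were 30.5% and 4.06%. The difference between the top and bottom groups was 19.9 percentage points (95% interval 15.9 to 23.8, permutation p = 1e-05, the smallest that 100000 draws allow). The core read backwards also fell, from 16.2% to 7.72%, a difference of 8.49 percentage points.

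The CHR core TTYGAA (Y is C or T), the element bound by the DREAM subunit LIN-54, was concentrated at the strongest peaks, among them those of lin-9, lin-54, lin-53, pcn-1 and cdk-1. Over all peaks it lay within 50 bp of 34.4% of summits and of 32.5% of displaced windows, a difference of 1.88 percentage points that did not pass the test (95% interval −0.232 to 3.997, exact McNemar test, p = 0.0863). In groups by strength, chosen after the data were seen, the share in the top 20% was 59.2% against 29.0% (exact McNemar test, p = 7.19e-31), and that in the bottom 20% was 28.5% against 33.4% (p = 0.0443). The core read backwards was at 12.7% of the top 20% of summits, below the 17.8% of their displaced windows (exact McNemar test, p = 0.00636). Against GC-matched promoters without a peak, the share over all peaks was higher (34.4% against 17.8%, Fisher's exact test, p = 8.01e-62). In the replicate 1 list alone it was also higher than in displaced windows (42.4% against 31.0%, exact McNemar test, p = 9.53e-25). In the reproducible list, the share within 25 bp was lower than in displaced windows (difference −3.61 percentage points, exact McNemar test, p = 1.08e-05). In the top 20%, CHR cores were most frequent 25 to 50 bp from the summit, at 0.273 and 0.271 per peak on either side. Within 25 bp they were at 0.0954 on each side. At the remaining peaks the values were 0.0955 and 0.106 farther out, and 0.0713 and 0.0781 within 25 bp.

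**Figure D3:**
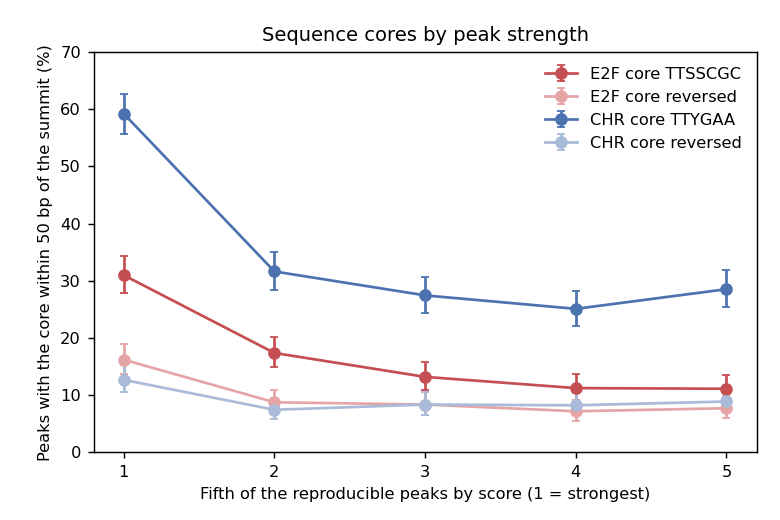
Percent of reproducible peaks with a sequence core within 50 bp of the summit (y axis) in 5 groups of peaks ordered by score (x axis, strongest first), with 95% Wilson intervals as error bars. The CHR core falls from 59.2% to 28.5% and the E2F core from 31.0% to 11.1%, and the reversed controls lie below both.

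Both cores occurred together more often than by chance, a test chosen after the data were seen. Of the 3824 peaks, 354 had an E2F and a CHR core within 50 bp of the summit, and 2221 (58.1%) had neither (odds ratio 2.84, 95% interval 2.39 to 3.37, Fisher's exact test, p = 2.53e-32). In the top 20%, 20.9% had both and 30.7% had neither (odds ratio 1.66, 95% interval 1.21 to 2.29, Fisher's exact test, p = 0.0019). In the bottom 20%, 6.15% had both and 66.5% had neither. The odds ratio there was higher, at 3.66 (95% interval 2.31 to 5.79, Fisher's exact test, p = 3.85e-08), a difference that was not tested. In the top 20%, 160 peaks had both cores, and 40 peaks held a CHR core directly before an E2F core. In the bottom 20% these numbers were 47 and 21. The odds ratios include such adjoining cores and were not computed without them. The peaks of citk-2 and dld-1, ranked 1 and 3 in the genome, had neither, and those of tba-2, Y53F4B.11 and F48A11.4 had both.

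The loci named in the transgene differed from each other. The gene unc-119 (WBGene00006843, chromosome III 10902641 to 10908935) held 4 reproducible peaks along its length, with scores of 41.5, 763, 58.1 and 78.5. The strongest, at 10905171 to 10905523, lay between the first 2 annotated exons and ranked 444 in the genome, and the summit of the last lay in a coding exon. The efl-1 gene (WBGene00001161, chromosome V 16958590 to 16965675) overlapped no entry of the reproducible, pooled or replicate lists used here. The nearest pooled-list entries left a stretch of 73.8 kb without any, from 16912138 to 16985968.

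**Figure D4:**
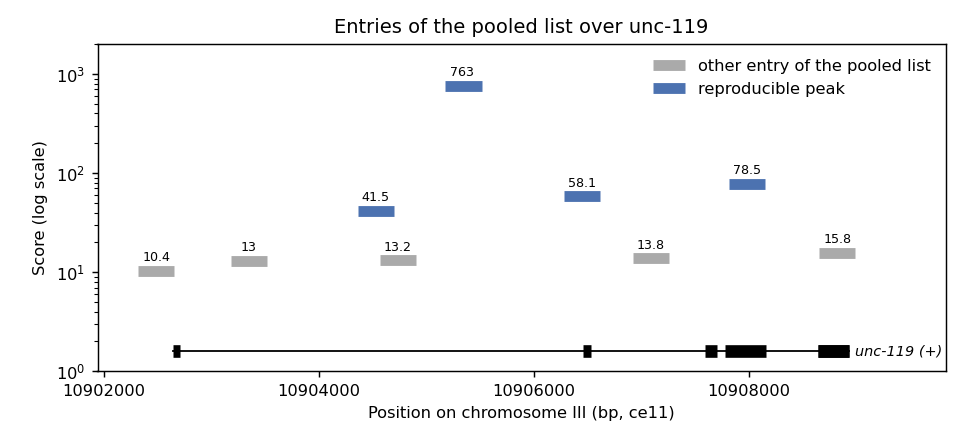
Entries of the pooled list over unc-119, drawn at their position on chromosome III (x axis, bp in ce11) and their score in the authors' units (y axis, log scale), with the gene's exons as black boxes. The 4 reproducible peaks (blue) have scores of 41.5 to 763, and the other entries (grey) 10.4 to 15.8.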

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

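The tests of replicate 1 against replicate 2 below had their bounds set before their values were seen, and the look at replicate 2 entries outside the reproducible list was chosen after the data were seen.

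A signal was present in data that the report's comparisons do not use. Of the 8332 replicate 2 entries at the highest −log10 q of that list, 4460 overlapped no reproducible peak. Their summits were in promoters in 29.3% of cases against 14.2% at random, and held the E2F core in 8.97% of cases against 4.04% in displaced windows. The CHR core was less frequent than in displaced windows (23.6% against 35.8%), and 25.36% overlapped an entry of replicate 1 against 18.8% at shifted positions.

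Replicate 1 had 1196 entries with a −log10 q above 2 and replicate 2 had 12800, and where both lists had an entry for a reproducible peak the replicate 2 score was higher at 2903 of 2911. Binding at other sites in replicate 1 is argued against, since 99.7% of those 1196 entries overlapped such an entry of replicate 2, and 8.70% did so after a shift of position. The same 99.7% is in line with weaker enrichment of the same sites in replicate 1, which may come from the immunoprecipitation or from depth. The lists do not tell these apart, since they give no read counts, and their scores may not share a scale. With 1 group, no biological explanation was tested.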

How the results depend on the processing

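All alternatives below were chosen before the data were examined, except the peaks supported in each replicate, which were chosen after the data were seen. Over those chosen before, values of the main results kept their direction and side of the threshold in 53 cases, moved in 8, newly passed the threshold in 4 and reversed in 2, and those of single gene lists kept them in 165, no longer passed in 11, newly passed in 4 and reversed in 12. With support in each replicate, main results kept them in 6 cases, moved in 2 and newly passed in 1, and single lists kept them in 21, no longer passed in 3 and reversed in 4. In every alternative the promoter share (44.9% to 84.8%), the E2F difference (6.17 to 23.8 percentage points), its change with strength (8.36 to 26.4) and the X odds ratio (0.106 to 0.462) kept theirs, and 7 to 10 gene lists were above other genes. The CHR difference (1.88 in the report) was 1.36 to 11.4 without 1 replicate, 13.2 in the stronger 50% of peaks, 23.0 with support in each replicate, 3.45 with windows displaced by 1000 bp and 16.6 against GC-matched promoters, and it reversed to −3.61 within 25 bp and −0.314 within 100 bp. Support in each replicate left 1385 genes with a promoter peak, as fewer peaks must. Lists below other genes were 4 with the wider promoter and 1 against genes with a pooled-list entry (2 in the report). Lists with stronger peaks (5 in the report) were 2 in the stronger 50%, 3 with the narrower promoter and 0 with support in each replicate. The stronger 50% and support in each replicate select on the score that these ratios compare. Replicate 1 agreement was 43.0% with a reciprocal overlap of 50% and 50.2% by summits, and replicate 2 agreement 77.1% and 92.9%, as stricter matching must lower them. Odds ratios reversed for meiosis (0.954 to 1.246 without 1 replicate, 2.03 with the wider and 1.135 with the narrower promoter), germ granule genes (1.13 with the wider promoter), muscle (0.409 to 1.06 without 1 replicate, 1.03 by nearest start) and neuron genes (1.44 by nearest start). Score ratios reversed for chemoreceptor genes (0.466 to 9.27 without 1 replicate, 0.703 by nearest start). In the stronger 50% they reversed for small RNA (0.943), proteasome (0.927) and oxidative phosphorylation genes (0.826), and with support in each replicate for those (0.889, 0.694 and 0.659) and ribosomal protein genes (0.724). A list with fewer than 5 bound members under an alternative gave no score ratio there. Except where stated, the cause was not tested. No paired analysis was possible because there was 1 group. With 2 libraries, no split could be counted and no outlier test was possible, and the unknown depth limits what the weak peaks can show.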

Other observations

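The tests of cores per gene list, of the CHR core at ribosomal protein genes, of the transgene loci, of the spacing and order of the cores and of repeat copies were chosen after the data were seen. The tests of the E2F core at ribosomal protein genes and of other active promoters were set before their values were seen.

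Core shares at the promoter peaks of each list were compared with those of all other promoter peaks, and these tests do not compare the lists with each other. At DNA replication genes, 23 of 36 promoter peaks (63.9%) had the E2F core within 50 bp of the summit against 16.6% of other promoter peaks (Fisher's exact test, adjusted p = 5.77e-09 over 24 tests), and at mitosis and chromosome segregation genes 28 of 46 did (60.9%, Fisher's exact test, adjusted p = 7.27e-10). Cell cycle regulators had it at 6 of 11 (54.5%, Fisher's exact test, adjusted p = 0.0225). By the same exact test, CHR shares were higher than at other promoter peaks, with 63.9% of DNA replication peaks (adjusted p = 0.00379), 69.6% of mitosis peaks (adjusted p = 2.18e-05) and 9 of 11 cell cycle peaks (adjusted p = 0.0109), where all promoter peaks had 35.6%. Strong peaks have more cores in general (59.2% CHR and 31.0% E2F in the top 20% of all peaks), and 26 of the 36 replication, 34 of the 46 mitosis and 7 of the 11 cell cycle peaks were in the top 20%. Cores were therefore also permuted among promoter peaks within 20 groups of like score (20000 permutations), a test chosen after the data were seen. The E2F core remained in excess at replication genes (mean of permutations 9.73 peaks, adjusted p = 0.0012 by this permutation test over 24 tests) and mitosis genes (mean 12.2, same adjusted p), and the CHR core at mitosis genes (32 peaks, mean 22.2, permutation test, adjusted p = 0.00864). The E2F share of cell cycle peaks and the CHR shares of replication and cell cycle peaks did not pass it (permutation test, adjusted p = 0.226, 0.293 and 0.0638). Those excesses are therefore not separated from peak strength. The cores read backwards were not tested per list, so the excesses are not shown to be specific to these sequences.

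In other groups an excess passed Fisher's exact test for the CHR core and not for the E2F core, whose intervals still allow one. Neither CHR excess passed the permutation among promoter peaks of like score, so neither is separated from peak strength. DNA repair and checkpoint peaks had CHR at 59.3% (Fisher's exact test, adjusted p = 0.0471) and E2F at 22.2% (odds ratio 1.44, 95% interval 0.595 to 3.49, adjusted p = 0.645). Of the 27 peaks, 20 were in the top 20%, where 59.2% of all peaks have CHR. Among peaks of like score, the 16 with CHR compared with a mean of 12.7 (permutation test, adjusted p = 0.521). Small RNA peaks had CHR at 9 of 13 (69.2%, Fisher's exact test, adjusted p = 0.0471) and E2F at 1 of 13 (odds ratio 0.567, 95% interval 0.104 to 3.10, adjusted p = 0.898). Among peaks of like score, the 9 with CHR compared with a mean of 4.39 (permutation test, adjusted p = 0.0552). Of the 5 DREAM peaks, 4 had CHR and 0 had E2F (Fisher's exact test, adjusted p = 0.125 and 0.793), with CHR cores at −27 bp from the summit at lin-9, 14 bp at lin-54, 43 bp at lin-53 and 28 bp at dpl-1. For chromatin regulator peaks no difference from other peaks was detected (Fisher's exact test, E2F 21.1%, adjusted p = 0.911; CHR 52.6%, adjusted p = 0.296), nor for those of proteasome, oxidative phosphorylation, histone and chemoreceptor genes (lowest adjusted p 0.301). Ribosomal protein peaks had fewer E2F cores than other peaks (6.25%, Fisher's exact test, adjusted p = 0.0471) and a CHR share of 23.4% (adjusted p = 0.111). Among promoter peaks of like score both cores were fewer. The E2F core was at 4 peaks against a mean of 14.4 (permutation test, adjusted p = 0.0056), and the CHR core at 15 against 26.2 (adjusted p = 0.00864).

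Ribosomal protein genes, a comparison list, held peaks among the strongest in the genome, rpl-3 second of all. Recruitment through the E2F core as the route common to the list is argued against, since its share of promoter peaks was lower than at DNA replication genes (difference in percentage points −57.6, 95% bootstrap interval −74.3 to −40.6), and likewise for the CHR core (−40.5, interval −58.5 to −21.2), though 15 of the 64 peaks, that of rpl-3 among them, have a CHR core and 4 an E2F core. A signal common to active promoters may contribute. The median score of bound proteasome and oxidative phosphorylation genes was 1.38 times that of all bound genes, inside the 0.679 to 1.56 of random draws, which leaves that explanation open. No other biological explanation was tested.

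The marker unc-119 held 4 reproducible summits, and of 1621 protein-coding genes of similar length 100% had fewer, the highest of them 3. Extra copies of the gene from the inserted transgene may raise read counts along it, but this stays open, since the 4 summits were seen before the test, any cause of peaks along the gene gives the same count, and copy number was not measured. At efl-1, 1.39% of protein-coding gene starts lay in pooled-list stretches without entries at least as long as the one around it, which argues against a gap of ordinary frequency. The cause of the gap was not tested, and entries over this region may be absent from the lists used here. With no second strain, no biological explanation was tested for either locus.

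A hypothesis from these data is that EFL-1 and LIN-54 sites adjoin, with the CHR core directly before the E2F core on one strand. Of 315 pairs of the cores on the same strand within 50 bp of a summit, 100 had the CHR start 6 or 7 bp before the E2F start. Pairs on opposite strands were not counted. In 1000 reassignments of CHR positions among windows, the mean was 10.2 such pairs and the highest count 20 (share 0.000999, the smallest possible). Reassignment breaks up an arrangement that also occurs away from peaks. This share therefore argues against random placement of the cores only, and does not show that adjoining pairs go with binding. A further 29 pairs had the CHR start 15 bp before, a spacing that was not tested, and 0 of their 29 windows held an adjoining pair, so adjoining cores do not account for it. One example is TTTGAATTGCCGC at tba-2 (chromosome I 12966960 to 12966972, minus strand). Another is TTCGAATTTCGCGC at mcm-7, a gene chosen after its values were seen (chromosome V 4347018 to 4347031, minus strand). Of the 97 peaks with an adjoining pair, only that of mcm-7 was the strongest promoter peak of a DNA replication gene. For mitosis and chromosome segregation genes the number was 0, and for DREAM genes 0. The arrangement was thus rare in the replication and mitosis lists, where each core was common. The arrangement is also abundant away from peaks, at 4558 places in the genome, of which 2.22% (95% interval 1.83% to 2.69%) were at summits, against 762 of all 38841 E2F cores and 3 of the 73 places with the opposite order (4.11%, Fisher's exact test between the orders, p = 0.225). Within promoters, 48 of 255 such places (18.8%) were at summits against 481 of 5211 E2F cores (9.23%), and of places with flanks unlike any other copy 82 of 979 were (8.38%), 45 of 149 in promoters (30.2%), differences that were not tested. The order was not shown to go with binding, and 78.5% of the 4558 have flanks that match another copy in at least 80% of the 15 bp on each side. At summits this share was 18.8%, between the bounds set for and against copies of a dispersed repeat, so repeats may account for part of the sites at summits. For the 48 places in promoters at summits it was lower, at 6.25% (3 places). That is below the bound set against repeats, though the bounds were set for all pairs at summits.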
